A study of Mus musculus with 12 samples.

How the data were processed

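The samples were 12 RNA libraries from layer 2 or layer 3 projection neurons of wild-type mouse cerebral cortex at postnatal days 3 and 7, with 3 biological replicates per group. Per the labels' protocols, neurons were labelled with mCherry by timed in utero electroporation and sorted by fluorescence from 2 to 3 pups per replicate. Their RNA was isolated with an RNeasy mini kit and made into libraries with a SMART-Seq mRNA LP kit. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCm39, and StringTie and featureCounts were used for assembly and counting, with no version, strand setting or treatment of shared reads stated. The deposited table holds the TPM (transcripts per 1000000) that the authors computed from these reads, for 56734 genes in 12 columns. Each column summed to 1000000, so the values keep no read depth, and the depth of each library and the precision it gives are unknown. Reads shared between closely related genes leave the levels of such genes uncertain. The table has no entry for mCherry, so the reporter was not measured. Gene coordinates were not used, since the annotation at hand was GENCODE vM21 on another build. Raw reads were not used here.

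Groups were taken from the sample labels. Of 30388 genes above 0 in any library, the 17606 with at least 1 TPM in at least 3 libraries were kept. Values were transformed to log2(TPM + 1), which shrinks the fold changes of low genes, and fitted with 1 mean per group in limma-trend (limma 3.58.1 in R 4.3.3), leaving 8 residual degrees of freedom. The 6 comparisons were layer 2 against layer 3 at P3, at P7 and as the mean over the ages, P7 against P3 in layer 2 and in layer 3, and the age change in layer 2 minus that in layer 3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so single genes rest on the moderated model.

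Cell types and gene functions were examined with 30 fixed lists: neuron identity by layer, other cell types, synaptic and channel genes, immature neuron, wiring, matrix, metabolic, chromatin, ribosomal, mitochondrial and sex-linked genes. Lists with at least 5 tested members were tested with camera at its preset inter-gene correlation of 0.01, with adjustment over the 30 lists of a comparison. Each was tested again with an estimated correlation and with fry. Members were also counted with the adjustment made over the list alone. A library's list score was the mean log2(TPM + 1) of the members. The lists, the groups, the comparisons, the thresholds and the other settings listed next, unless said otherwise, were set before the data were examined.

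The genes named were, for each comparison, up to 5 with the largest positive and 5 with the largest negative log2 fold change among called genes. These had to have TPM ranges that did not overlap between the groups, a mean of at least 5 TPM in the higher group and a symbol other than a predicted or clone name. For the mean over the ages the ranges had to be apart at both ages, and for the difference of age changes no range condition applied. Added to them were up to 3 called members in each direction of each list described, and the identity checks Cux1, Cux2, Pou3f2, Slc17a7, Rorb, Bcl11b, Fezf2, Tbr1, Gad1, Gad2, Dcx, Camk2a, Aqp4, Mbp, Cx3cr1 and Cldn5. Some genes under the rule are not reported here. Genes named outside this rule are said to have been chosen after their values were seen, and Ttr in the report was chosen so.

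The pipeline was tested on simulated data with the size of the real table and 200 changed genes, in 20 draws per comparison. Changes of 2 on the log2 scale were recovered in 93.6% of genes and changes of 1 in 46.9% for layer 2 against layer 3 at P3, with 5.05% false calls. The other comparisons between 2 groups gave 93.9%, 94.0% and 94.5% for changes of 2. A list shifted by 0.5 was recovered in 20 of 20 draws. The simulated genes varied independently of each other, so the draws do not test list calls where the members of a list are correlated.

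Other settings were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-ratio scaling, quantile normalization, removal of mitochondrial, ribosomal protein and haemoglobin genes, robust moderation, array weights, a fit of the compared groups alone, a replicate block, an absolute log2 fold change of at least 1, an adjusted p under 0.1 for overlaps, and each library left out in turn. A fit without 3 libraries that stood apart and fits with marker scores as covariates were chosen after seeing the data. Overlaps of calls were compared with the product of the call rates. Other splits of the libraries into groups of the same sizes were counted, all 10 for 3 against 3 and 100 drawn for the comparisons over 4 groups.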

Results

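Polyadenylated RNA was sequenced from projection neurons of layer 2 and layer 3 of the mouse cerebral cortex at postnatal day 3 (P3) and postnatal day 7 (P7). The neurons carried the red fluorescent protein mCherry, introduced by timed electroporation in utero, and were collected by fluorescence-activated sorting. Each of the 4 groups had 3 libraries, and each library came from a separate pool of 2 to 3 wild-type pups. Layer and age were taken from the sample labels. The names of the layer 3 libraries carry the number 14 and those of layer 2 the number 15, and the sources do not say what these stand for. If they are the embryonic day of electroporation, time since labelling differed between the layers in every library. Levels are in transcripts per 1000000 (TPM), which keep no read depth, so the depth of each library is unknown. Between 15349 and 16948 genes reached 1 TPM in a library, and 17606 genes were tested. The sources state no aim beyond profiling these neurons, so the comparisons asked which genes differed between the layers at each age and which changed between the ages in each layer. Values after ± are SDs of 3 libraries for TPM and list scores, and standard errors for log2 fold changes. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes.

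Bcl11b, which marks subcerebral neurons, averaged 5.11 ± 0.816, 3.51 ± 2.13, 1.70 ± 0.652 and 3.50 ± 1.72 TPM in P3 layer 2, P3 layer 3, P7 layer 2 and P7 layer 3. In the same order Gad1, the GABA-synthesising enzyme of interneurons, averaged 8.79 ± 3.95, 3.99 ± 1.09, 9.31 ± 4.64 and 12.5 ± 9.83 TPM. Transcripts of other cell types were present in every group. Microglia markers had a mean log2(TPM + 1) score of 7.22 ± 0.58 in P3 layer 2 and 6.61 ± 0.86 in P7 layer 3. Astrocyte markers scored 5.60 ± 0.15, 4.27 ± 0.66, 5.68 ± 0.80 and 5.14 ± 1.00 in the order above, and cell cycle genes 5.0 ± 0.14, 3.61 ± 0.47, 3.75 ± 0.46 and 3.22 ± 0.53. Correlations between libraries of a group ranged from 0.961 to 0.982 and those between groups from 0.878 to 0.975, with no identical pair. The first principal component held 40.4% of the variance and separated P3 from P7, and the second held 18.8%. P3 layer 2 replicate 2 had the highest microglia score (7.88) and the highest erythroid score (6.63). P3 layer 3 replicate 1 lay at 67.6 on the second component and held 234 TPM of Ttr, a choroid plexus transcript that reached at most 2.20 TPM elsewhere. P7 layer 3 replicate 1 had the highest oligodendrocyte lineage score (5.59) and held 462 TPM of Mbp, a myelin gene.

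**Figure D1:**
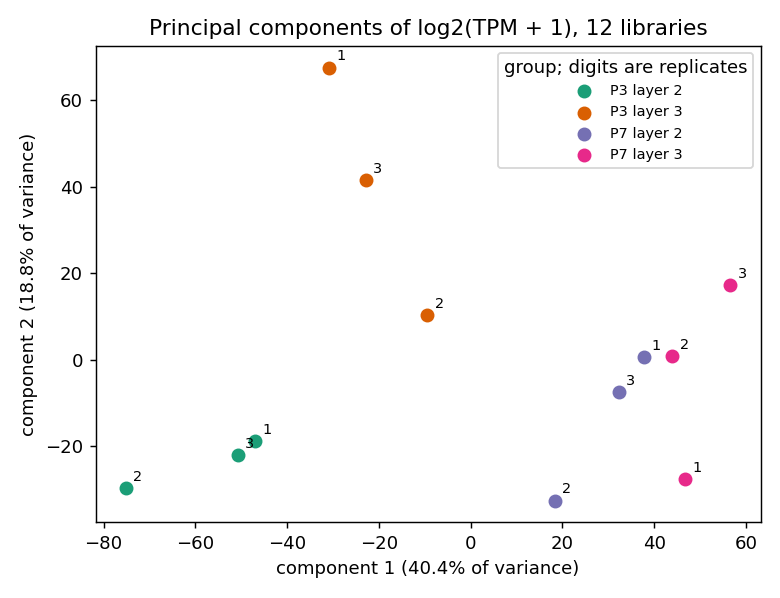
Each point is 1 of the 12 libraries, placed by its scores on the first principal component (x axis, 40.4% of the variance) and the second (y axis, 18.8%) of log2(TPM + 1). The first component separates P3 from P7, and P3 layer 3 replicate 1 lies highest on the second at 67.6.

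At P3, libraries of layer 2 held less of the layer 4 regulator Rorb than those of layer 3, less of some synaptic and channel genes, and more of some cell cycle, progenitor, glial and cilium genes. Rorb averaged 7.40 ± 2.18 TPM in layer 2 and 56.1 ± 27.1 TPM in layer 3 (log2 fold change -2.66 ± 0.34, adjusted p = 0.000677). The G-protein signalling regulator Rgs13 (0.724 ± 0.349 against 17.4 ± 7.55 TPM, adjusted p = 0.000769), the homeobox gene Msx3 (1.47 ± 1.25 against 24.7 ± 4.09 TPM, adjusted p = 0.00018) and the secreted peptide gene Ostn (6.25 ± 5.86 against 48.2 ± 10.6 TPM, adjusted p = 0.00605) were also lower in layer 2. Dynlrb2, which encodes a dynein light chain of cilia, averaged 128 ± 67.8 TPM in layer 2 and 11.9 ± 0.857 TPM in layer 3 (log2 fold change 3.20 ± 0.43, adjusted p = 0.000871). The cilium genes Pifo (3.11 ± 0.40, adjusted p = 0.000725), Cfap141 (3.06 ± 0.51, adjusted p = 0.00308), Lrrc46 (3.02 ± 0.36, adjusted p = 0.000508) and Ppp1r32 (3.01 ± 0.50, adjusted p = 0.003) were higher in layer 2 as well. Eif2s3y and Ddx3y, which lie on the Y chromosome, were lower in layer 2 (-4.37 ± 0.81 and -3.05 ± 0.55, adjusted p = 0.00548 and 0.00446) and were listed at 0 in P3 layer 2 replicates 1 and 2. The sex of the pups is not given in the sources used here. All P3 layer 3 libraries held Eif2s3y (23.7 to 98.9 TPM), so Y transcripts were not balanced between the layers at P3. An effect of pup sex on the other genes called at P3 cannot be told apart from layer here and was not tested. The same P3 layer 2 libraries enter the age change in layer 2, the mean over the ages and the difference of age changes. An effect of pup sex there was not tested either.

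Upper-layer genes were called lower in layer 2 as a list at P3. Of 24, 1 was higher, 9 were lower and 14 were not called (2 higher and 11 lower adjusted over the list alone). Their median log2 fold change was -0.47 (camera adjusted p = 4.25e-07, adjusted p = 0.315 with an estimated correlation). For comparison, 12 neuron-restricted immature neuron genes, chosen after seeing the data, had a median of -0.38. Whether a lower share of neuronal RNA accounts for the upper-layer list was not tested. Inhba, a subunit of activin (-1.67 ± 0.17), the POU factor Pou3f1 (-1.61 ± 0.22), the semaphorin receptor Plxnd1 (-1.53 ± 0.19) and the homeobox genes Cux1 (-0.84 ± 0.17) and Cux2 (-1.01 ± 0.18) were lower. Pou3f2 (-0.22 ± 0.18, adjusted p = 0.499) was not called. Of 18 deep-layer markers the repressor gene Bcl6 was lower (-1.51 ± 0.22, adjusted p = 0.00136) and the list was not called (median 0.12, adjusted p = 0.716). Layer 2/3 subtype markers of adult cortex were not called (median -0.03, mean 0.03, adjusted p = 0.716). Nor were the layer 4 markers as a list (median log2 fold change -0.55, camera adjusted p = 0.199), of which Rorb is a member.

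Lists of synaptic and channel genes were called lower in layer 2 at P3, although most of their members were not called. Of 24 presynaptic release genes, 9 were lower and 15 were not called (0 higher and 16 lower adjusted over the list alone), with a median of -0.50 (camera adjusted p = 3.85e-11, adjusted p = 0.315 with an estimated correlation). Examples were the vesicular glutamate transporter Slc17a6 (-1.66 ± 0.22), the complexin Cplx2 (-1.07 ± 0.15) and the syntaxin Stx1a (-1.02 ± 0.13). Of 25 postsynaptic genes, 6 were lower and 19 were not called (0 higher and 7 lower adjusted over the list alone). As a list their median was -0.43 (camera adjusted p = 9.25e-06, adjusted p = 0.347 with an estimated correlation). The calmodulin-binding Nrgn averaged 185 ± 57.3 TPM in layer 2 and 774 ± 189 TPM in layer 3 (-2.08 ± 0.21, adjusted p = 0.000204), and the kinase gene Camk2a was lower as well (-1.01 ± 0.15, adjusted p = 0.00151). Of 33 potassium and HCN channel genes, 1 was higher, 7 were lower and 25 were not called (3 higher and 15 lower adjusted over the list alone). They had a median of -0.47 (camera adjusted p = 2.64e-07, adjusted p = 0.444 with an estimated correlation), with Kcnh1 (-1.71 ± 0.27) and Kcnip2 (-1.45 ± 0.18) as examples. GABA-A receptor subunits and chloride transporters, of which 5 were lower and 9 were not called (1 higher and 8 lower adjusted over the list alone), had a median of -0.64 (camera adjusted p = 0.000396, adjusted p = 0.481 with an estimated correlation). The chloride exporter Slc12a5 (-1.10 ± 0.17) was lower. Of 25 sodium and calcium channel genes, 3 were lower and 22 were not called (0 higher and 6 lower adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.000198, adjusted p = 0.481 with an estimated correlation). Of 21 glutamate receptors, 5 were lower and 16 were not called (0 higher and 5 lower adjusted over the list alone), Grm2 (-1.61 ± 0.21) among them. Their median was -0.03 (camera adjusted p = 0.029, adjusted p = 0.481 with an estimated correlation), and the call ended without P3 layer 2 replicate 2, P3 layer 3 replicate 2 or P3 layer 3 replicate 3 (adjusted p = 0.112, 0.0916 and 0.0534) or with array weights (0.0523). Of 31 immature neuron genes, 3 were higher, 4 were lower and 24 were not called (4 higher and 13 lower adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.00114, adjusted p = 0.481 with an estimated correlation). The astrocyte score differed between the same libraries, at 5.60 ± 0.15 in layer 2 and 4.27 ± 0.66 in layer 3. The guidance genes Sema7a (-2.22 ± 0.24) and Epha8 (-1.88 ± 0.28), the cadherin Cdh6 (-1.93 ± 0.21) and the neuropeptide genes Adcyap1 (-2.35 ± 0.29) and Cck (-1.68 ± 0.33) were lower. Their lists were not called and had medians and means of opposite sign: axon guidance 0.12 and -0.05 (adjusted p = 0.158), cadherins 0.04 and -0.05 (adjusted p = 0.332), and neuropeptides 0.07 and -0.02 (adjusted p = 0.556).

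Lists of cell cycle, progenitor and glial genes were called higher in layer 2 at P3. Of 16 cell cycle genes, 12 were higher and 4 were not called (15 higher and 0 lower adjusted over the list alone). The list median was 1.45 (camera adjusted p = 1.75e-10, adjusted p = 0.347 with an estimated correlation). The cyclin Ccnb1 (2.19 ± 0.45, adjusted p = 0.00949) and the mitotic kinase gene Aurkb (1.75 ± 0.34, adjusted p = 0.00666) were among them. Of 10 progenitor and radial glia markers, 9 were higher and 1 was not called (10 higher and 0 lower adjusted over the list alone). Their median was 1.61 (camera adjusted p = 2.25e-08, adjusted p = 0.315 with an estimated correlation). Fabp7, a fatty acid binding protein of radial glia, averaged 4805 ± 1378 TPM in layer 2 and 1066 ± 531 TPM in layer 3 (adjusted p = 0.00981, and 0.0528 without P3 layer 2 replicate 2). Of 15 astrocyte markers, 7 were higher and 8 were not called (11 higher and 1 lower adjusted over the list alone), with a median of 1.71 (camera adjusted p = 5.28e-05, adjusted p = 0.481 with an estimated correlation). The astrocyte gene Mlc1 was higher (2.28 ± 0.53, adjusted p = 0.0179), but not without P3 layer 2 replicate 2, P3 layer 3 replicate 1 or P3 layer 3 replicate 3 (adjusted p = 0.0674, 0.0695 and 0.0565). Aqp4, the astrocyte water channel, was not called (2.08 ± 0.70, adjusted p = 0.0801), except without P3 layer 3 replicate 2 or P7 layer 3 replicate 1 (0.0145 and 0.0486). Of 14 oligodendrocyte lineage markers, 3 were higher and 11 were not called (6 higher and 0 lower adjusted over the list alone), with a median of 1.24 (camera adjusted p = 0.00114, adjusted p = 0.562 with an estimated correlation) and with Lhfpl3 (1.32 ± 0.27) as an example. Of 17 interneuron markers, 4 were higher and 13 were not called (7 higher and 0 lower adjusted over the list alone), with a median of 0.91 (camera adjusted p = 0.00149, adjusted p = 0.524 with an estimated correlation) and with the homeobox gene Dlx2 (1.92 ± 0.31) as an example. Microglia (median log2 fold change 0.62, camera adjusted p = 0.0747), vascular (median log2 fold change -0.05, camera adjusted p = 0.374) and erythroid lists (median log2 fold change 0.54, camera adjusted p = 0.218) were not called.

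Ribosomal protein, cholesterol, matrix and sex-linked lists were also called at P3. Of 81 ribosomal protein genes, 3 were higher and 78 were not called (1 higher and 0 lower adjusted over the list alone). In the list the median was 0.25 (camera adjusted p = 6.45e-07, adjusted p = 0.562 with an estimated correlation). That call ended without P3 layer 3 replicate 2 (adjusted p = 0.352). Cholesterol biosynthesis genes were called higher (median 0.25, camera adjusted p = 0.0145, adjusted p = 0.562 with an estimated correlation), but not without P3 layer 2 replicate 1, P3 layer 2 replicate 3 or P3 layer 3 replicate 3 (0.0586, 0.0564 and 0.0771). Matrix genes were called higher (median 0.74, camera adjusted p = 0.0163, adjusted p = 0.481 with an estimated correlation), but not without P3 layer 2 replicate 3 or P3 layer 3 replicate 3 (0.0564 and 0.0571). The sex-linked genes were called lower (median -1.31, camera adjusted p = 0.013, adjusted p = 0.315 with an estimated correlation), but not without P3 layer 3 replicate 1 (0.0611). Respiratory chain genes (adjusted p = 0.317), mitochondrially encoded mRNAs (0.602), immediate early genes (0.0896) and chromatin genes (0.798, median 0.06 with a downward test) were not called. With limma, 1593 genes differed between the layers at P3, 857 higher and 736 lower in layer 2, and 17 of 30 lists were called with camera. The share called higher was 53.8%, against 46.1% with median-ratio scaling, 45.9% with quantile normalization, 39.3% without P3 layer 3 replicate 1, 44.6% without P3 layer 2 replicate 1, 43.3% without P3 layer 2 replicate 2 and 45.1% without P3 layer 3 replicate 3. It was 64.9% without P3 layer 3 replicate 2, 65.03% in a fit of these groups alone and 68.7% at an absolute log2 fold change of at least 1. The gene count was 668 without P3 layer 2 replicate 2, 927 without P3 layer 2 replicate 3, 991 without P3 layer 3 replicate 3 and 935 in a fit of these groups alone. It was 597 without the 3 libraries that stood apart, with 31.8% higher, and Ostn, Eif2s3y, Ddx3y, Cux1, Ccnb1, Fabp7, Mlc1 and Cck were not called. The interneuron (adjusted p = 0.0604), glutamate receptor (0.0509) and sex-linked calls (0.134) ended there too. With the astrocyte score as a covariate it was 311, and Ppp1r32, Eif2s3y, Ddx3y, Cux1, Cck, Ccnb1, Aurkb, Mlc1 and Lhfpl3 were not called. The calls of the astrocyte (adjusted p = 0.0915), interneuron (0.357), oligodendrocyte lineage (0.347, with its direction turned), immature neuron (0.262), glutamate receptor (0.0685), sodium and calcium channel (0.0546), cholesterol (0.188), matrix (0.23) and sex-linked lists (0.22) ended with it. Both of these settings were chosen after seeing the data. The astrocyte score is the mean of the astrocyte markers themselves, so the end of their own call with it tells nothing about that call.

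**Figure D2:**
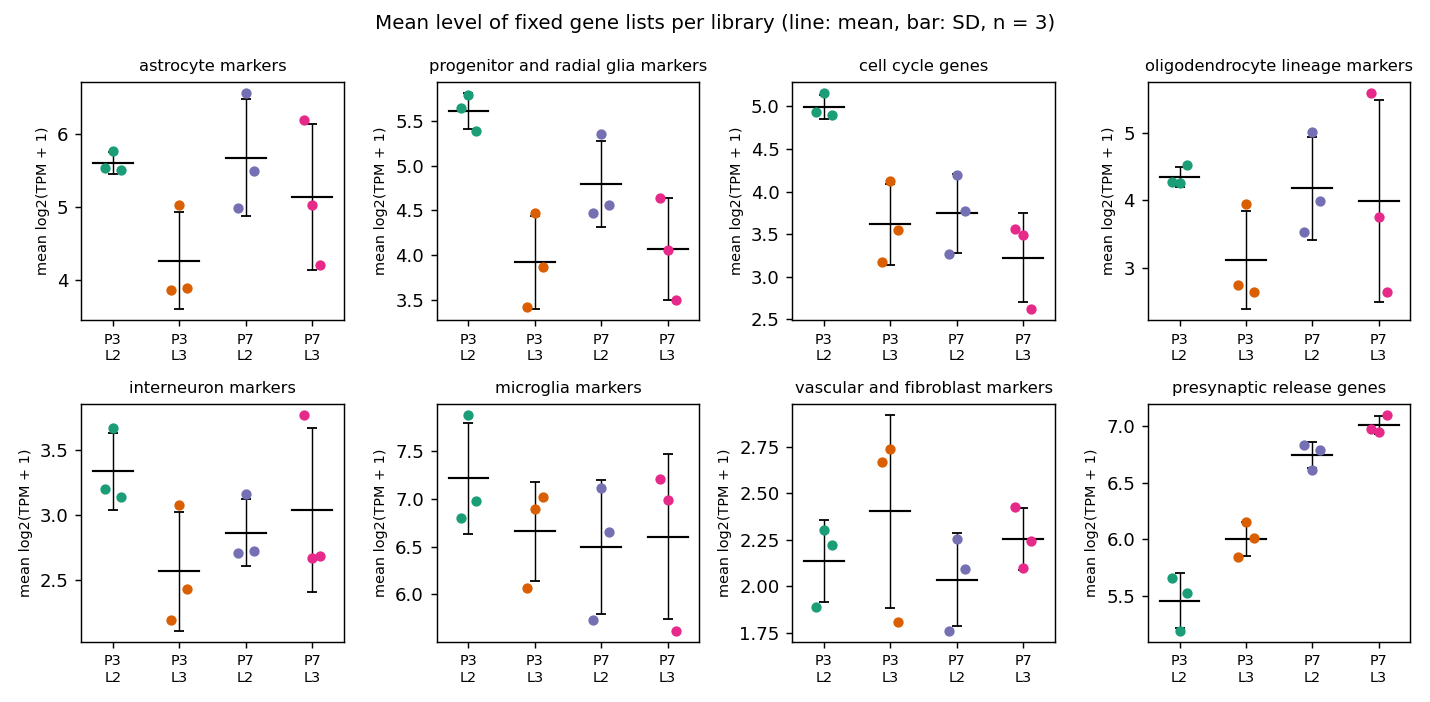
Points are libraries and the y axis is the mean log2(TPM + 1) of the members of each of 8 gene lists, with group means and SDs (n = 3, x axis: group). Progenitor markers averaged 5.61 in P3 layer 2 and 3.92 in P3 layer 3, and presynaptic release genes 5.46 and 6.0.

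At P7, Rorb was again lower in layer 2 than in layer 3. It averaged 6.28 ± 0.875 TPM in layer 2 and 60.7 ± 17.9 TPM in layer 3 (log2 fold change -3.05 ± 0.34, adjusted p = 0.00124). The fibroblast growth factor gene Fgf9 (1.41 ± 0.979 against 15.6 ± 4.63 TPM, adjusted p = 0.00262) and the glutamate receptor gene Grm2 (7.20 ± 0.887 against 25.7 ± 5.86 TPM, adjusted p = 0.00433) were lower in layer 2. The melanocortin receptor gene Mc4r was higher (19.2 ± 4.16 against 3.87 ± 0.350 TPM, adjusted p = 0.00486). Rorb, Fgf9, Grm2 and Mc4r kept their calls whichever library was left out. Rgs13 (-2.82 ± 0.44, adjusted p = 0.0129), the kainate receptor gene Grik1 (-3.01 ± 0.51, adjusted p = 0.0217) and the organic cation transporter Slc22a3 (-2.56 ± 0.42, adjusted p = 0.0197) were lower in layer 2. The Rgs13 call ended without P7 layer 2 replicates 2 or 3 or P7 layer 3 replicates 2 or 3 (0.053 to 0.0753). The Grik1 call ended without P7 layer 2 replicates 1 or 3 or P7 layer 3 replicates 2 or 3 (0.0734 to 0.105), and the Slc22a3 call without P7 layer 2 replicate 2 or P7 layer 3 replicates 2 or 3 (0.054 to 0.0984). The cilium genes Dynlrb2 (2.36 ± 0.43, adjusted p = 0.0286) and Tmem212 (2.10 ± 0.39, adjusted p = 0.0332) were higher in layer 2. The Dynlrb2 call ended without any P7 layer 2 replicate or P7 layer 3 replicates 1 or 3 (0.053 to 0.142), and the Tmem212 call without P3 layer 2 replicate 3, P7 layer 2 replicates 1 or 2 or any P7 layer 3 replicate (0.0547 to 0.145). Ptx3, a pentraxin (1.59 ± 0.30, adjusted p = 0.0382), and Thg1l, a tRNA guanylyltransferase (1.43 ± 0.26, adjusted p = 0.0282), were also higher. The Ptx3 call ended without P3 layer 2 replicates 1 or 3, P3 layer 3 replicate 3, any P7 layer 2 replicate or any P7 layer 3 replicate (0.0549 to 0.179), and the Thg1l call without any P7 layer 2 replicate or P7 layer 3 replicates 1 or 2 (0.0783 to 0.124). Slc17a7, the vesicular glutamate transporter of mature cortex, averaged 171 ± 37.1 TPM in layer 2 and 321 ± 36.4 TPM in layer 3 (adjusted p = 0.0286). Camk2a (-0.82 ± 0.15, adjusted p = 0.0332) and the LIM protein gene Lmo4 (-1.37 ± 0.27, adjusted p = 0.0432) were lower as well. The Slc17a7 call ended without P7 layer 2 replicates 2 or 3 or any P7 layer 3 replicate (0.0642 to 0.151). The Camk2a call ended without any P7 layer 2 replicate or any P7 layer 3 replicate (0.0744 to 0.187), and the Lmo4 call without P3 layer 2 replicate 1, P3 layer 3 replicate 3, any P7 layer 2 replicate or any P7 layer 3 replicate (0.057 to 0.187). Cux1, Cux2 and Bcl11b were not called at P7 (adjusted p = 0.904, 0.928 and 0.562).

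Few members of any list passed at P7. Of 5 layer 4 markers Rorb was lower and 4 were not called (0 higher and 3 lower adjusted over the list alone). Their median was -1.11 (camera adjusted p = 0.000115, adjusted p = 0.147 with an estimated correlation). Of 24 upper-layer genes, 3 were lower and 21 were not called (3 higher and 8 lower adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.00226, adjusted p = 0.584 with an estimated correlation). Of 24 presynaptic genes, 1 was higher, 1 was lower and 22 were not called (1 higher and 6 lower adjusted over the list alone). The list median was -0.25 (camera adjusted p = 9.41e-05, adjusted p = 0.584 with an estimated correlation). Slc17a7 was lower in that list. Of 21 glutamate receptors, 2 were lower and 19 were not called (0 higher and 3 lower adjusted over the list alone). Their median was -0.30 (camera adjusted p = 0.0028, adjusted p = 0.584 with an estimated correlation). Of 14 GABA-A receptor and chloride transporter genes, none passed with limma (0 higher and 6 lower at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.00101, adjusted p = 0.584 with an estimated correlation). Potassium channel genes were called lower (camera adjusted p = 0.00543, adjusted p = 0.645 with an estimated correlation), but not without P7 layer 2 replicate 2 or P7 layer 3 replicate 3 (0.125 and 0.0836). Neuropeptide genes were called lower too (camera adjusted p = 0.00543, adjusted p = 0.584 with an estimated correlation), but not without P7 layer 2 replicate 2 (0.0516). Deep-layer markers were called lower (camera adjusted p = 0.0442, adjusted p = 0.645 with an estimated correlation), but not without P7 layer 3 replicate 1 (0.518), P7 layer 2 replicate 2 (0.104), P7 layer 2 replicate 3 (0.186), P3 layer 2 replicate 1 (0.0509), P3 layer 3 replicate 1 (0.0665) or P3 layer 3 replicate 2 (0.0612), nor with a pseudocount of 0.1 (0.0624), array weights (0.237) or a fit of these groups alone (0.116). Without the 3 libraries that stood apart the adjusted p was 0.682, and with the astrocyte score as a covariate the potassium channel and astrocyte calls ended (0.0501 and 0.211). Both settings were chosen after seeing the data, and the astrocyte score is made of the astrocyte markers themselves, so it cannot test their own call. Of the progenitor markers none passed with limma (3 higher and 0 lower at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone). As a list their median was 0.74 (camera adjusted p = 1.95e-05, adjusted p = 0.584 with an estimated correlation). Of the cell cycle genes none passed with limma (3 higher and 0 lower at an unadjusted p under 0.05, 1 higher and 0 lower adjusted over the list alone). Their median was 0.48 (camera adjusted p = 6.29e-05, adjusted p = 0.584 with an estimated correlation). Astrocyte markers were called higher (camera adjusted p = 0.0027, adjusted p = 0.645 with an estimated correlation), but not without P7 layer 2 replicate 2 or P7 layer 3 replicate 3 (0.336 and 0.326). Ribosomal protein genes (median 0.21, camera adjusted p = 3.64e-10, adjusted p = 0.584 with an estimated correlation), respiratory chain genes (median 0.13, camera adjusted p = 2.67e-05, adjusted p = 0.645 with an estimated correlation), mitochondrially encoded mRNAs (median 0.23, camera adjusted p = 4.47e-06, adjusted p = 0.584 with an estimated correlation) and cholesterol genes (median 0.13, camera adjusted p = 0.0027, adjusted p = 0.615 with an estimated correlation) were called higher. With limma, 88 genes differed at P7, 21 higher and 67 lower in layer 2, against 1746 at an unadjusted p under 0.05. The share called higher was 23.9%, against 14.6% without P7 layer 2 replicate 1, 38.1% without P7 layer 2 replicate 3 and 47.1% without P7 layer 3 replicate 3. The gene count ranged from 14 without P7 layer 2 replicate 2 to 125 without P3 layer 3 replicate 2. It was 41, 21, 23 and 17 without P7 layer 2 replicate 1, P7 layer 2 replicate 3, P7 layer 3 replicate 2 and P7 layer 3 replicate 3. It was 47 with a pseudocount of 0.1 and 147 with a pseudocount of 5.

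Rorb and Rgs13 differed between the layers at both ages. Of the genes called at P3 and at P7, 10 were higher and 30 were lower in layer 2 both times, and 3 had opposite directions. The product of the call rates was 1.02 and 2.80. Both comparisons share each gene's variance estimate, so this product can understate the overlap that chance gives. Fold changes at P3 and at P7, which share no library, correlated at 0.325 across genes. Averaged over the ages, Rgs13 (-3.09 ± 0.31, adjusted p = 0.000129), Rorb (-2.86 ± 0.24, adjusted p = 3.57e-05), Ostn (-2.77 ± 0.41, adjusted p = 0.00121), Fgf9 (-2.43 ± 0.24, adjusted p = 0.000121) and Msx3 (-2.25 ± 0.25, adjusted p = 0.000227) were lower in layer 2. The cilium genes Dynlrb2 (2.78 ± 0.30, adjusted p = 0.000216), Tmem212 (2.36 ± 0.28, adjusted p = 0.00033), Dynlt4 (2.34 ± 0.30, adjusted p = 0.000522) and Odf3b (2.30 ± 0.30, adjusted p = 0.000664) were higher, as was Got1l1 (2.21 ± 0.43, adjusted p = 0.00739). Cux1 (-0.47 ± 0.12, adjusted p = 0.0286), Cux2 (-0.55 ± 0.13, adjusted p = 0.0191, and 0.0569 without P7 layer 2 replicate 2) and Slc17a7 (-0.79 ± 0.12, adjusted p = 0.00144) were lower. The Cux1 call ended without P3 layer 2 replicates 2 or 3, P3 layer 3 replicate 1, P7 layer 2 replicate 2 or P7 layer 3 replicates 2 or 3 (0.0512 to 0.0809). Of 24 presynaptic genes, 10 were lower and 14 were not called (1 higher and 19 lower adjusted over the list alone), with a median of -0.39 (camera adjusted p = 3.6e-11, adjusted p = 0.33 with an estimated correlation). Of 24 upper-layer genes, 9 were lower and 15 were not called (0 higher and 13 lower adjusted over the list alone). The list median was -0.34 (camera adjusted p = 7.02e-07, adjusted p = 0.33 with an estimated correlation). All 10 progenitor markers were higher, Fabp7 (1.68) and Pax6 (1.55) among them (10 higher and 0 lower adjusted over the list alone). Their median was 1.07 (camera adjusted p = 1.27e-09, adjusted p = 0.33 with an estimated correlation). In all, 1396 genes passed for the mean difference with limma, 710 higher and 686 lower in layer 2, and 20 lists were called with camera. The share called higher was 50.9%, against 42.1% without P3 layer 3 replicate 1, 59.6% without P3 layer 3 replicate 2 and 71.8% at an absolute log2 fold change of at least 1. The gene count was 798 without P7 layer 2 replicate 2, 885 without P3 layer 2 replicate 2, 920 without P7 layer 3 replicate 2 and 823 without P7 layer 3 replicate 3. It was 368 with the astrocyte score as a covariate, a setting chosen after seeing the data.

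**Figure D3:**
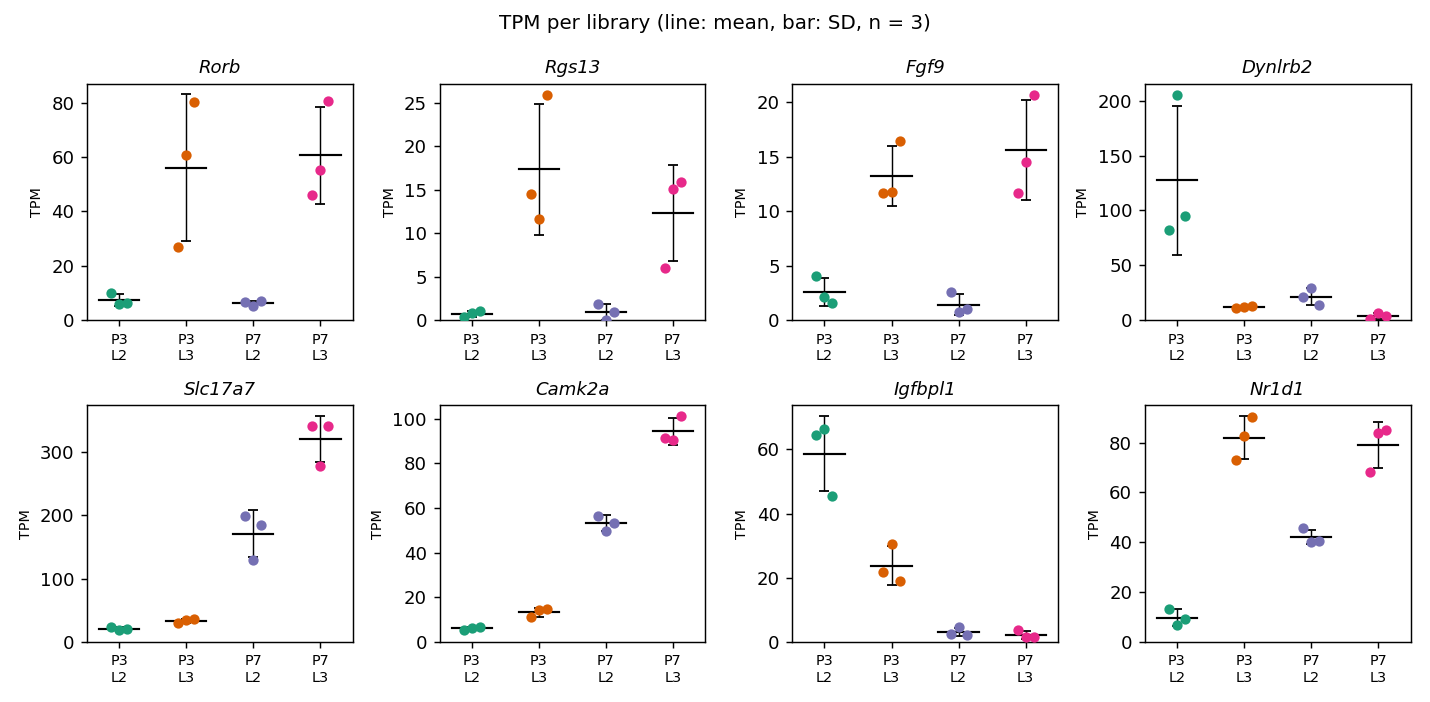
Points are libraries, lines are group means and bars are SDs (n = 3) of TPM (y axis) in the 4 groups (x axis) for Rorb, Rgs13, Fgf9, Dynlrb2, Slc17a7, Camk2a, Igfbpl1 and Nr1d1. Mean Rorb was 7.40 and 56.1 TPM in layers 2 and 3 at P3, and 6.28 and 60.7 TPM at P7.

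Between P3 and P7, many transcripts of synapses and channels rose in the layer 2 libraries and most cell cycle genes fell. Snhg11, a neuronal long noncoding RNA, rose from 7.36 ± 2.08 to 245 ± 61.2 TPM (log2 fold change 4.88 ± 0.49, adjusted p = 1.45e-05). The channel subunit Cacng3 rose from 4.98 ± 1.57 to 127 ± 14.4 TPM (4.45 ± 0.33, adjusted p = 1.28e-06), and the matricellular gene Ccn3 from 17.9 ± 4.05 to 365 ± 32.0 TPM (4.30 ± 0.25, adjusted p = 2.29e-07). Lamp5, a lysosomal membrane gene of upper layers, rose as well (4.16 ± 0.22, adjusted p = 1.3e-07). BC023719 was listed at 0 in all P3 layer 2 libraries and at 52.4, 2.43 and 42.8 TPM in P7 layer 2 (adjusted p = 0.0227). Its adjusted p was 0.0527, 0.0641, 0.0566, 0.0976 and 0.0919 without P3 layer 2 replicates 1, 2 or 3, P7 layer 2 replicate 1 or P7 layer 2 replicate 3. Igfbpl1, which is expressed in newly born neurons, fell from 58.7 ± 11.6 to 3.03 ± 1.34 TPM (-3.92 ± 0.31, adjusted p = 2.08e-06). Spp1 (-4.53 ± 0.65, adjusted p = 0.000269) and Gpnmb (-3.41 ± 0.62, adjusted p = 0.00131), which reactive microglia express, fell beside the microglia gene Tyrobp (-1.77 ± 0.47, adjusted p = 0.0135). The adjusted p of Tyrobp was 0.0718 without P3 layer 2 replicate 2 and 0.0689 without P7 layer 2 replicate 1. The cilium gene Cfap141 (-3.07 ± 0.51, adjusted p = 0.000762) and Ly6g6e (-3.34 ± 0.26, adjusted p = 1.96e-06) also fell. The Y chromosome genes Eif2s3y (3.96 ± 0.81, adjusted p = 0.00319) and Ddx3y (3.24 ± 0.55, adjusted p = 0.000841) rose in layer 2. In layer 3 they were not called (adjusted p = 0.322 and 0.574). An effect of pup sex on the other age changes called in layer 2 cannot be told apart from age here and was not tested.

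Most synaptic and channel genes rose in layer 2. Of 33 potassium and HCN channel genes, 26 rose, 1 fell and 6 were not called (28 up and 1 down adjusted over the list alone), with a median of 1.13 (camera adjusted p = 2.12e-12, adjusted p = 0.255 with an estimated correlation). Kcnj9 (3.23) and Kcnip2 (2.57) were examples. Of 24 presynaptic genes, 19 rose and 5 were not called (23 up and 0 down adjusted over the list alone). In the list the median was 1.00 (camera adjusted p = 4.84e-15, adjusted p = 0.255 with an estimated correlation). Slc17a7 rose from 20.9 ± 2.78 to 171 ± 37.1 TPM (adjusted p = 1.77e-07). Of 25 postsynaptic genes, 18 rose, 1 fell and 6 were not called (19 up and 1 down adjusted over the list alone), with a median of 0.86 (camera adjusted p = 1.73e-08, adjusted p = 0.255 with an estimated correlation), and Camk2a (2.95) and Lrrtm4 (3.57) rose. Of 14 GABA-A receptor and chloride transporter genes, 11 rose and 3 were not called (11 up and 0 down adjusted over the list alone), with a median of 1.32 (camera adjusted p = 9.83e-07, adjusted p = 0.323 with an estimated correlation), and Slc12a5 (2.49) rose. Of 25 sodium and calcium channels, 15 rose and 10 were not called (16 up and 0 down adjusted over the list alone), with a median of 0.88 (camera adjusted p = 1.81e-06, adjusted p = 0.323 with an estimated correlation), and Scn1a (1.61) rose. Of 21 glutamate receptors, 9 rose, 1 fell and 11 were not called (10 up and 1 down adjusted over the list alone). Their median was 0.76 (camera adjusted p = 0.00123, adjusted p = 0.323 with an estimated correlation). Cadherins (median 0.50, camera adjusted p = 0.00347, adjusted p = 0.668 with an estimated correlation), such as Cdh9 (2.10), were called higher at P7. So were layer 2/3 subtype markers (median 1.12, camera adjusted p = 0.00347, adjusted p = 0.255 with an estimated correlation), such as Calb1 (2.63). Upper-layer genes were not called as a list (median 0.00, mean 0.11, adjusted p = 0.971), with Cpne6 (2.79) rising and Inhba (-0.72) falling. Bcl11b fell (-1.20 ± 0.35, adjusted p = 0.0249), but not without P3 layer 2 replicates 2 or 3 or P7 layer 2 replicates 2 or 3 (0.0917, 0.0569, 0.0635 and 0.0954).

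Ribosomal protein genes fell in layer 2. Of 81, 1 rose, 70 fell and 10 were not called (1 up and 74 down adjusted over the list alone), with a median of -0.83 (camera adjusted p = 3.31e-32, adjusted p = 0.255 with an estimated correlation). Of 78 respiratory chain genes, 1 rose, 22 fell and 55 were not called (1 up and 24 down adjusted over the list alone), with a median of -0.35 (camera adjusted p = 3.36e-08, adjusted p = 0.622 with an estimated correlation) and with Ndufa12 (-0.97) as an example. Of 16 cell cycle genes, 12 fell and 4 were not called (0 up and 15 down adjusted over the list alone), with a median of -1.19 (camera adjusted p = 6.47e-08, adjusted p = 0.351 with an estimated correlation). Of 10 progenitor markers, 1 rose, 3 fell and 6 were not called (1 up and 3 down adjusted over the list alone). The list median was -0.81 (camera adjusted p = 0.0222, adjusted p = 0.696 with an estimated correlation). Nes (-1.74) fell and Hopx rose (1.00), and the progenitor call ended without P7 layer 2 replicate 1 (adjusted p = 0.0559). Interneuron markers were called lower (camera adjusted p = 0.0311, adjusted p = 0.745 with an estimated correlation), but not without P3 layer 2 replicate 2, P7 layer 2 replicate 1 or P7 layer 2 replicate 3 (0.112, 0.0559 and 0.0584). Microglia markers were called lower (camera adjusted p = 0.0161, adjusted p = 0.745 with an estimated correlation), but not without P3 layer 2 replicate 2 or P7 layer 2 replicate 1 (0.0975 and 0.125). Without the 3 libraries that stood apart, chosen after seeing the data, the interneuron and microglia calls ended as well (adjusted p = 0.103 and 0.112). Mitochondrially encoded mRNAs were called lower (camera adjusted p = 0.0416, adjusted p = 0.752 with an estimated correlation), but not without P3 layer 2 replicates 2 or 3 or P7 layer 2 replicates 2 or 3 (0.0561, 0.0924, 0.0777 and 0.0657), nor with quantile normalization (0.36) or the astrocyte score as a covariate (0.0555, chosen after seeing the data). Median and mean differed in sign for layer 4 (-0.03 and 0.28), astrocyte (-0.16 and 0.08), immature neuron (0.07 and -0.20) and matrix lists (-0.13 and 0.25), none of them called. With limma 4280 genes changed, 2638 rising and 1642 falling, and 15 lists were called with camera. Without P3 layer 2 replicate 2 the gene count was 2799, and with the astrocyte and microglia scores as covariates, chosen after seeing the data, it was 2347.

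In the layer 3 libraries some synaptic and channel genes also rose between P3 and P7, and some immature neuron genes fell. Snhg11 rose from 17.6 ± 13.8 to 467 ± 104 TPM (log2 fold change 5.0 ± 0.49, adjusted p = 2.64e-05), and the vesicular zinc transporter Slc30a3 from 4.25 ± 0.503 to 95.6 ± 11.8 TPM (4.20 ± 0.36, adjusted p = 8.97e-06). The neuropeptide precursor Cartpt (4.01 ± 0.37, adjusted p = 1.84e-05), the orphan receptor gene Gpr6 (3.97 ± 0.26, adjusted p = 9.87e-07) and the matrix gene Npnt (3.82 ± 0.23, adjusted p = 7.17e-07) rose. Igfbpl1 fell from 23.8 ± 6.02 to 2.16 ± 1.24 TPM (-3.01 ± 0.31, adjusted p = 3.26e-05). The activin-binding Fst (-3.38 ± 0.35, adjusted p = 3.26e-05), Msx3 (-3.37 ± 0.35, adjusted p = 3.66e-05) and Ly6g6e (-4.00 ± 0.26, adjusted p = 9.87e-07) fell. Ptgds, which is abundant in meninges and choroid plexus, fell (-3.81 ± 1.26, adjusted p = 0.0467). Its adjusted p was 0.21, 0.108, 0.136 and 0.0605 without P3 layer 3 replicate 1 or P7 layer 3 replicates 1, 2 or 3, and 0.0571, 0.0556 and 0.0529 without P3 layer 2 replicate 3 or P7 layer 2 replicates 2 or 3. The fibroblast genes Col1a1 (-2.10 ± 0.50) and Dcn (-1.98 ± 0.51) fell beside it, and P3 layer 3 replicate 1 held 23.2 and 90.2 TPM of them. The astrocyte water channel Aqp4 rose (2.25 ± 0.70, adjusted p = 0.0354), but not without P3 layer 3 replicate 1, P3 layer 3 replicate 3 or P7 layer 3 replicate 1 (0.16, 0.11 and 0.159).

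Lists of synaptic and channel genes were called higher at P7 in layer 3. Between the same libraries the astrocyte and oligodendrocyte lineage lists had medians of 0.86 and 1.07 and were not called. Of 33 potassium and HCN channel genes, 19 rose and 14 were not called (21 up and 0 down adjusted over the list alone), with a median of 0.82 (camera adjusted p = 2.69e-08, adjusted p = 0.317 with an estimated correlation), and Kcnc4 (2.77) rose. Of 24 presynaptic genes, 13 rose, 1 fell and 10 were not called (17 up and 1 down adjusted over the list alone). Their median was 0.70 (camera adjusted p = 1.25e-07, adjusted p = 0.317 with an estimated correlation). Slc17a7 rose from 33.4 ± 3.07 to 321 ± 36.4 TPM. Cplx2 fell (-0.55, adjusted p = 0.0173), but not without P3 layer 3 replicates 1 or 3 or P7 layer 3 replicates 1 or 2 (0.0532, 0.077, 0.0525 and 0.054). Of 25 postsynaptic genes, 11 rose, 2 fell and 12 were not called (14 up and 2 down adjusted over the list alone), with a median of 0.57 (camera adjusted p = 7.16e-05, adjusted p = 0.317 with an estimated correlation). Camk2a (2.75) and Lrrtm4 (2.40) rose. Of 14 GABA-A receptor and chloride transporter genes, 9 rose and 5 were not called (14 up and 0 down adjusted over the list alone), with a median of 1.34 (camera adjusted p = 5.15e-07, adjusted p = 0.317 with an estimated correlation), and Slc12a5 (1.65) rose. Of 25 sodium and calcium channels, 13 rose and 12 were not called (14 up and 1 down adjusted over the list alone), with a median of 0.75 (camera adjusted p = 0.000174, adjusted p = 0.317 with an estimated correlation), and Scn1a (1.68) rose. Of 21 glutamate receptors, 9 rose and 12 were not called (14 up and 1 down adjusted over the list alone), with a median of 0.88 (camera adjusted p = 0.000145, adjusted p = 0.317 with an estimated correlation), and Grik1 (2.48) rose. Cadherins (median 0.76, camera adjusted p = 0.000914, adjusted p = 0.423 with an estimated correlation) and layer 2/3 subtype markers (median 1.21, camera adjusted p = 0.000308, adjusted p = 0.317 with an estimated correlation) were called higher at P7, with Cdh13 (1.95) and Calb1 (3.09) rising. Neuropeptide genes were called higher as well (median 0.67, camera adjusted p = 0.00447, adjusted p = 0.317 with an estimated correlation), with Scg2 (2.43) and Crh (1.47) rising.

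Immature neuron genes were called lower at P7 in layer 3. Of 31, 4 rose, 13 fell and 14 were not called (5 up and 14 down adjusted over the list alone). As a list their median was -0.18 (camera adjusted p = 1.14e-05, adjusted p = 0.317 with an estimated correlation). Sox4 (-1.74) and Sox11 (-1.59) fell and Neurod1 (1.30) rose. Of 81 ribosomal protein genes, 64 fell and 17 were not called (0 up and 69 down adjusted over the list alone), with a median of -0.75 (camera adjusted p = 2.42e-40, adjusted p = 0.317 with an estimated correlation) and with Rps19 (-1.33) as an example. Of 78 respiratory chain genes, 1 rose, 29 fell and 48 were not called (1 up and 37 down adjusted over the list alone), with a median of -0.36 (camera adjusted p = 4.38e-15, adjusted p = 0.317 with an estimated correlation) and with Atp5e (-0.86) as an example. Of 13 mitochondrially encoded mRNAs, 4 fell and 9 were not called (0 up and 7 down adjusted over the list alone). Their median was -0.40 (camera adjusted p = 3.03e-06, adjusted p = 0.317 with an estimated correlation). Upper-layer genes were called lower at P7, with a median of -0.31 (camera adjusted p = 0.0134, adjusted p = 0.317 with an estimated correlation) and a mean of 0.05. Gfra2 (2.46) and Lmo4 (1.84) rose in that list and Inhba (-1.62) and Pou3f3 (-1.08) fell, and without P7 layer 3 replicate 1 the adjusted p was 0.093. With the astrocyte score as a covariate, chosen after seeing the data, it was 0.0801. Cell cycle genes were called lower (camera adjusted p = 0.00397, adjusted p = 0.556 with an estimated correlation), but not without P3 layer 3 replicate 2 or P7 layer 3 replicate 3 (0.0779 and 0.0798). Chromatin genes were called lower (camera adjusted p = 0.0298, adjusted p = 0.317 with an estimated correlation), but not without P3 layer 3 replicate 2, P3 layer 3 replicate 3 or P7 layer 3 replicate 1 (0.0779, 0.0663 and 0.0912). Deep-layer (median 0.20, adjusted p = 0.7) and progenitor markers (median 0.23, adjusted p = 0.836) were not called and had tests that pointed down, and vascular markers had a median of 0.74 and a mean of -0.15. With limma 3670 genes changed in layer 3, 2539 rising and 1131 falling, and 16 lists were called with camera. With median-ratio scaling the split was 1739 rising and 1741 falling, and with quantile normalization 1726 and 1748, as the median of all genes moved by -0.17 and -0.19. The count was 2266 without P3 layer 3 replicate 1, 2117 in a fit of these groups alone, 2024 without the 3 libraries that stood apart and 1409 with the astrocyte and microglia scores as covariates. The last 2 settings were chosen after seeing the data, and Atp5e was not called without the 3 libraries.

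Snhg11, Slc17a7, Camk2a, Ccn3 and Lamp5 rose in both layers, and Igfbpl1, Ly6g6e and Inhba fell in both. In all 1563 genes rose and 696 fell in both layers, 14 changed in opposite directions, and the fold changes correlated at 0.617 across genes. The product of the call rates was 380 and 106, which can understate the overlap that chance gives, as the comparisons share each gene's variance estimate.

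**Figure D4:**
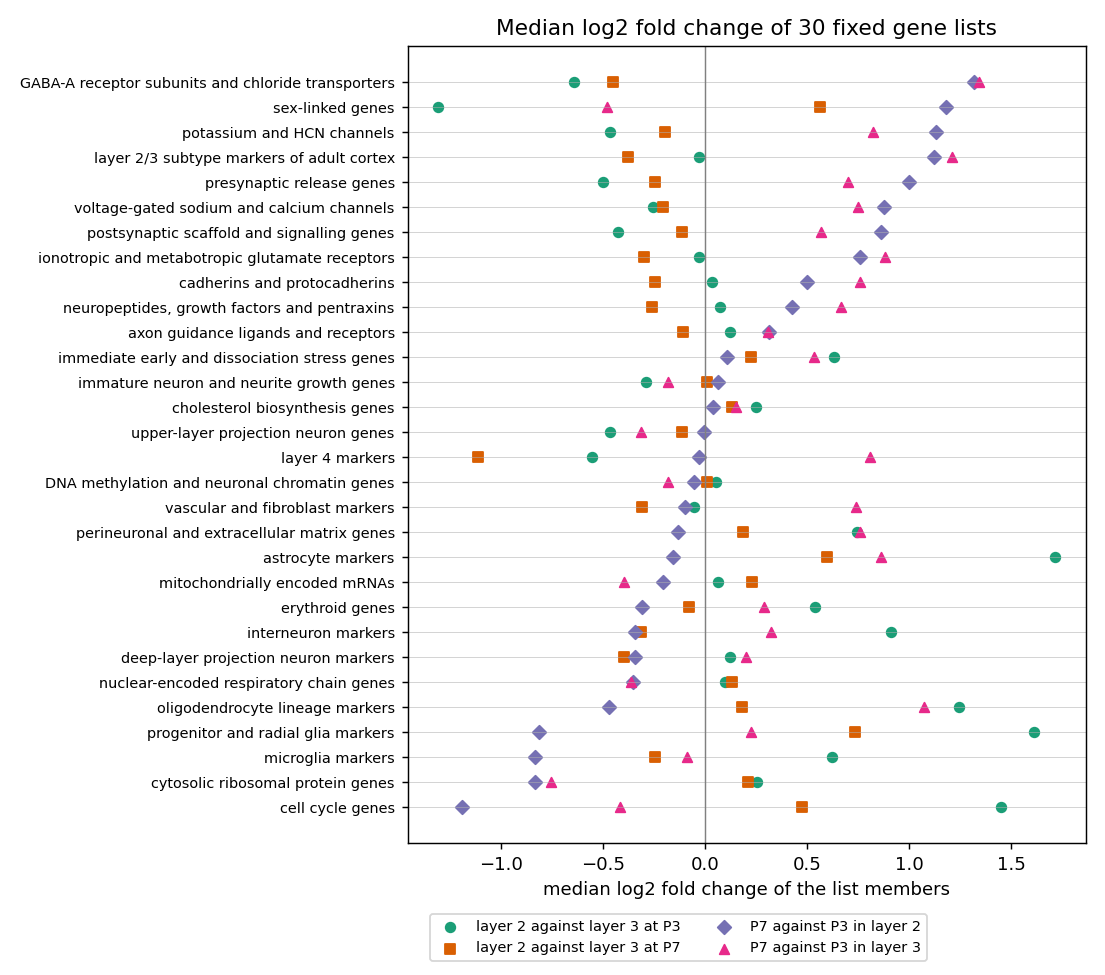
Each point is the median log2 fold change (x axis) of the members of 1 of 30 gene lists (y axis), for layer 2 against layer 3 at P3 and at P7 and for P7 against P3 in layer 2 and in layer 3. Presynaptic genes had medians of -0.50 and -0.25 between the layers and 1.00 and 0.70 between the ages.

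Few genes were called as changing with age by a different amount in the layers. Recovery of simulated changes was not measured for this comparison. Nr1d1, a clock gene, averaged 9.73 ± 3.36, 82.0 ± 8.75, 42.1 ± 3.00 and 79.0 ± 9.34 TPM in P3 layer 2, P3 layer 3, P7 layer 2 and P7 layer 3. Its age change in layer 2 minus that in layer 3 was 2.11 ± 0.28 (adjusted p = 0.0107). The differences for Bcl6 (2.35 ± 0.31, adjusted p = 0.0107) and the neuronal calcium sensor Vsnl1 (2.13 ± 0.22, adjusted p = 0.00128) were also positive. The neurofilament gene Nefl, with 27.4 ± 5.70 TPM in P7 layer 2 and 165 ± 46.7 TPM in P7 layer 3, had a negative difference (-2.85 ± 0.38, adjusted p = 0.0107). Nr1d1, Bcl6, Vsnl1 and Nefl kept their calls whichever library was left out. Krt12 (3.10 ± 0.56, adjusted p = 0.0449), Bmp2 (2.07 ± 0.33, adjusted p = 0.026) and Cplx2 (1.22 ± 0.21, adjusted p = 0.0397) had positive differences. The kinase gene Dapk2 (-2.88 ± 0.50, adjusted p = 0.0397), the caveolin Cav1 (-2.80 ± 0.47, adjusted p = 0.0397) and the cilium gene Rsph1 (-2.73 ± 0.47, adjusted p = 0.0397) had negative differences. The Krt12 call ended without P3 layer 2 replicates 2 or 3, P3 layer 3 replicates 1 or 3, any P7 layer 2 replicate or any P7 layer 3 replicate (0.0606 to 0.159), the Bmp2 call without P3 layer 2 replicate 3, P3 layer 3 replicate 1, any P7 layer 2 replicate or any P7 layer 3 replicate (0.0503 to 0.116) and the Cplx2 call without P3 layer 2 replicates 2 or 3, P3 layer 3 replicates 1 or 3, any P7 layer 2 replicate or any P7 layer 3 replicate (0.0564 to 0.143). The Dapk2 call ended without P3 layer 2 replicates 1 or 3, P3 layer 3 replicates 1 or 3, any P7 layer 2 replicate or any P7 layer 3 replicate (0.0534 to 0.109), the Cav1 call without P3 layer 2 replicates 1 or 3, P3 layer 3 replicates 1 or 3, any P7 layer 2 replicate or any P7 layer 3 replicate (0.0544 to 0.144) and the Rsph1 call without P3 layer 2 replicate 3, P3 layer 3 replicates 1 or 3, P7 layer 2 replicates 2 or 3 or any P7 layer 3 replicate (0.0672 to 0.144). Lmo4 had a negative difference (-2.52 ± 0.38, adjusted p = 0.0194), but not without P3 layer 2 replicate 3, P3 layer 3 replicate 1, P7 layer 3 replicate 1 or P7 layer 3 replicate 3 (0.0657, 0.0511, 0.0739 and 0.0637). Of the lists, cell cycle (median -0.85, camera adjusted p = 0.000142, adjusted p = 0.72 with an estimated correlation), progenitor (median -1.04, camera adjusted p = 0.00165, adjusted p = 0.72 with an estimated correlation) and interneuron genes (median -1.05, camera adjusted p = 0.000867, adjusted p = 0.72 with an estimated correlation) had negative differences. The progenitor and interneuron calls ended without the 3 libraries that stood apart (adjusted p = 0.259 and 0.592), a setting chosen after seeing the data. Presynaptic genes (median 0.28, camera adjusted p = 0.000142, adjusted p = 0.72 with an estimated correlation), postsynaptic genes (median 0.22, camera adjusted p = 0.000867, adjusted p = 0.72 with an estimated correlation) and potassium channel genes (median 0.24, camera adjusted p = 0.000912, adjusted p = 0.768 with an estimated correlation) had positive ones. Upper-layer genes were called with a median of 0.32 (camera adjusted p = 0.000912, adjusted p = 0.72 with an estimated correlation) and a mean of 0.06. In all 32 genes passed with limma, 21 positive and 11 negative, against 2015 at an unadjusted p under 0.05, and 13 lists were called with camera. The positive share was 65.6%, against 40.2% without P3 layer 3 replicate 2 and 39.9% with array weights, and the median of all genes was -0.09. The gene count ranged from 8 without P7 layer 3 replicate 1 to 102 without P3 layer 3 replicate 2. It was 13, 19, 13, 13, 15, 11, 13 and 13 without P3 layer 2 replicate 3, P3 layer 3 replicates 1 or 3, P7 layer 2 replicates 1, 2 or 3, or P7 layer 3 replicates 2 or 3. It was 14 with a pseudocount of 0.1 and 16 with no filter, and the median of all genes moved by 0.12 and 0.11 with median-ratio scaling and quantile normalization. None of the 96 list calls of the 6 comparisons held with an estimated correlation (4, 1, 4, 5, 2 and 1 lists had an unadjusted p under 0.05, in the order of the comparisons above). With fry, which tests whether the genes of a set move on balance in a single direction and does not compare them with other genes, 38 of the 96 held.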

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

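The counts over other splits of the libraries were set before the data were examined, and all tests of the 3 patterns below were chosen only after the patterns were seen. Among the genes, 11 stood out for changing with age by a different amount in the layers, given as the age change in layer 2 minus that in layer 3. Positive differences were found for Krt12 (3.10), Bcl6 (2.35), Vsnl1 (2.13), Nr1d1 (2.11), Bmp2 (2.07) and Cplx2 (1.22), and negative ones for Dapk2 (-2.88), Nefl (-2.85), Cav1 (-2.80), Rsph1 (-2.73) and Lmo4 (-2.52). Mean TPM in P3 layer 2, P3 layer 3, P7 layer 2 and P7 layer 3 was 81.0, 383, 684 and 748 for Vsnl1 and 18.4, 15.1, 27.4 and 165 for Nefl. The lists with such a difference, with their camera adjusted p, were upper-layer genes (0.000912), interneuron markers (0.000867), astrocyte markers (0.0403), progenitor markers (0.00165), cell cycle genes (0.000142), oligodendrocyte lineage markers (0.0183) and postsynaptic genes (0.000867). The others were presynaptic genes (0.000142), sodium and calcium channels (0.0244), potassium channels (0.000912), immature neuron genes (0.000457), mitochondrially encoded mRNAs (0.00708) and sex-linked genes (0.000912). None of the 13 held with an estimated correlation, where 1 list had an unadjusted p under 0.05, or with fry, where 1 did. The astrocyte call ended without P3 layer 2 replicate 2, P3 layer 3 replicates 1 or 3, P7 layer 2 replicates 1 or 3 or P7 layer 3 replicate 1 (0.0531 to 0.443). The oligodendrocyte lineage call ended without P3 layer 3 replicate 3, P7 layer 2 replicate 1 or P7 layer 3 replicate 1 (0.102 to 0.627), the sodium and calcium channel call without P3 layer 2 replicate 2, P3 layer 3 replicate 3, P7 layer 2 replicates 1 or 3 or P7 layer 3 replicate 2 (0.0601 to 0.196) and the mitochondrial call without P3 layer 3 replicate 3 (0.551). With quantile normalization the immature neuron and mitochondrial calls ended (0.071 and 0.177), with a pseudocount of 5 the astrocyte call (0.0743) and with no filter the sodium and calcium channel call (0.0514). Without the 3 libraries that stood apart, chosen after seeing the data, the interneuron, astrocyte, progenitor, oligodendrocyte lineage, sodium and calcium channel and immature neuron calls ended (0.592, 0.991, 0.259, 0.706, 0.259 and 0.183).

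Other splits of the libraries called fewer genes than the real groups, with the exception of the difference of age changes. The real counts and the highest of the other 9 splits were 1593 and 1 for the layers at P3, 88 and 1 at P7, 4280 and 1 for age in layer 2, and 3670 and 0 for age in layer 3, with 1 of 10 splits as large each time. For lists they were 17 and 17 (2 of 10 splits as large), 15 and 16 (4 of 10), 15 and 18 (4 of 10) and 16 and 16 (2 of 10). With 10 splits the share cannot fall under 0.05. For the mean difference between the layers, 1 of 100 splits reached the 1396 genes and the highest other had 551, so a random grouping is excluded at a share of 0.05. The 20 lists of that comparison were reached by 3 of 100 splits, a share under 0.05. The highest other split called 21, more than the real groups, so the count of lists alone is weak ground against a random grouping. For the difference of age changes, 5 of 100 splits reached 32 genes and the highest other had 551, so a random grouping is not excluded. The 4 others that reached it kept the P3 labels and exchanged 1 or 2 libraries between the layers at P7. The structure of the samples they share with the real groups is the layer difference at P3, and no further structure was tested. For lists, 36 of 100 splits reached 13, with 21 the highest other.

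The first pattern is the higher level of glial, progenitor, cell cycle and cilium genes in P3 layer 2 than in P3 layer 3, tested only after it was seen. Whether ependymal cells add the cilium genes stays open. The median of 3 ependymal genes outside the cilium was 1.66, where Mia (2.37) and Calml4 (1.66) were called and Rarres2 (1.40, adjusted p = 0.0903) was not. These genes were chosen after their values were seen, so their median cannot test it. A lower neuronal share that raises all other cell types alike is argued against by the layer difference of the astrocyte score exceeding that of the vascular score by 1.60 ± 0.35, and by 1.27 ± 0.15 without P3 layer 3 replicate 1, although it exceeded that of the microglia score by only 0.78 ± 0.46. RNA of glial and dividing cells carried through the sort, and progenitors or young glia that carry mCherry, remain open as hypotheses, and no separate test was run, since the lists that show the pattern cannot test it. Of their 55 markers, 45 reached 1 TPM in all 12 libraries.

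The next pattern is the lower level of 142 synaptic and channel genes in P3 layer 2 (median -0.43, 35 called lower), again tested only after it was seen. A lower share of neuronal RNA may contribute: the median of these genes minus that of 12 neuron-restricted immature genes was -0.0491. Below the lowest of the 12 (-0.55) lay 11 of the 142 genes, at an adjusted p under 0.05 over the 142. This argues against a uniform loss as the whole cause, and such a loss stays open as a part. At the same threshold, 14 lay below and 8 above the median of the 12. Both reference values were taken as fixed, without their own error, and the 12 genes were chosen after seeing the data. RNA of other cells, as far as the astrocyte score tracks it, is argued against as the whole cause, since the median was -0.36 with that score as a covariate. Of the 142 genes, 11 were then called lower, and the median standard error was 0.29, against 0.24 without the score. What lowered the number called was not tested. Less mature neurons in layer 2 cannot be told apart from no such difference: the layer difference at P3 correlated with the mean age change at -0.34 across 173 genes (-0.26 without the immature neuron genes, -0.19 at P7, -0.32 across all genes), and 5 of the 10 splits of the P3 libraries gave a value as far from 0, up to 0.46.

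The last pattern is the lower level of 5 of 7 clock genes in P3 layer 2, where the genes and the tests were chosen only after values were seen. Nr1d1 (-2.99 ± 0.20, adjusted p = 8.66e-06), Dbp (-2.04 ± 0.20, adjusted p = 0.00018), Hlf (-1.52 ± 0.20, adjusted p = 0.000769), Nr1d2 (-1.34 ± 0.29, adjusted p = 0.0116) and Ciart (-1.18 ± 0.20, adjusted p = 0.00311) were lower, and Tef (-0.32 ± 0.16, adjusted p = 0.236) and Per1 (-0.61 ± 0.23, adjusted p = 0.113) were not called. Another hour of collection is a possible explanation, under which genes of the opposite phase had to be higher. Arntl (-0.83 ± 0.23) and Npas2 (-1.08 ± 0.25) were lower, Clock (0.29 ± 0.37) was not, and their median was -0.83, against that prediction. The explanation stays open all the same, since a lower share of neuronal RNA could lower these genes at any hour. Arntl had a similar value at P7 (-0.78 ± 0.23), where it was not called (adjusted p = 0.203). Among the 7 clock genes, Hlf was called lower at P7 (-1.02 ± 0.20, adjusted p = 0.0411) and Nr1d1 was not (-0.89 ± 0.20, adjusted p = 0.0683). Dbp, Nr1d2, Tef, Per1 and Ciart were not called there either. For the mean over the ages, Nr1d1, Dbp, Hlf and Nr1d2 were called lower (adjusted p = 1.82e-05, 0.000358, 0.000227 and 0.0309), and Ciart, Tef and Per1 were not called. RNA of other cells, as far as the astrocyte score tracks it, is argued against as the whole cause, as the median of the 7 genes was -1.34 without and -1.28 with the astrocyte score as a covariate, where Nr1d1, Dbp, Hlf and Ciart stayed called and Nr1d2 (-1.28 ± 0.37, adjusted p = 0.104) did not, with a wider standard error. RNA of other cells that the score does not track and a difference between layer 2 and layer 3 neurons remain open and were not tested.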

How the results depend on the processing

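Of 399 calls of named genes, between 240 and 395 held under the settings that all of them could be tested in, and none turned direction. With median-ratio scaling 382 held, with quantile normalization 389, with a pseudocount of 0.1 366, with one of 5 389, with robust moderation 380, with no filter 315, with array weights 395 and at an absolute log2 fold change of at least 1 292. Of the 96 list calls, 94, 92, 94, 94, 96, 95 and 90 held under the first 7 of these. Without 1 library, 315 to 387 gene calls and 85 to 93 list calls held. Depth is unknown and limits what low genes can show. The fit of the compared groups alone was not run for the comparisons over 4 groups.

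Counts of called genes that moved by over 1.5 times follow, in the order layers at P3, layers at P7, age in layer 2, age in layer 3, mean layer difference and difference of age changes. With array weights they were 5210, 418, 6488, 7701, 3780 and 1103, against 1593, 88, 4280, 3670, 1396 and 32, and the cause was not tested. At an absolute log2 fold change of at least 1 they were 954, 1934, 1503 and 483 for the comparisons other than layers at P7 and the difference of age changes. In a fit of the compared groups alone they were 935 for layers at P3 and 2117 for age in layer 3, with fewer libraries. A pseudocount of 0.1 gave 47 for layers at P7 and 14 for the difference of age changes, a pseudocount of 5 gave 147 for layers at P7, and no filter gave 16 for the difference of age changes. The overlap of the layer calls at P3 and P7 held 90 genes at an adjusted p under 0.1, against 40. The share of calls higher in layer 2 at P3 was 53.8%, against 46.1% with median-ratio scaling, 45.9% with quantile normalization and 68.7% at an absolute log2 fold change of at least 1. The positive share of the difference of age changes was 65.6%, against 39.9% with array weights. The rising share in layer 3 was 69.2%, against 50% with median-ratio scaling and 49.7% with quantile normalization.

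Other settings were chosen after seeing the data. Without the 3 libraries that stood apart the counts were 597 for layers at P3, 2024 for age in layer 3 and 12 for the difference of age changes, whose called lists were 8, with fewer libraries. With the astrocyte score as a covariate they were 311 for layers at P3, 368 for the mean layer difference and 21 for the difference of age changes. With the astrocyte and microglia scores they were 492, 2347, 1409 and 564 for layers at P3, age in layer 2, age in layer 3 and the mean layer difference. Called lists at P3 were then 9 and 11. Some lists turned direction with the astrocyte score and with both scores: oligodendrocyte lineage markers at P3 (adjusted p = 0.347 and 0.246), interneuron markers for the mean layer difference (0.674 and 0.629) and oligodendrocyte lineage markers for the mean layer difference, called in the opposite direction (0.036 and 0.0116). Immature neuron genes for the mean layer difference turned with the astrocyte score (0.956). The cause was not tested.

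With an estimated correlation 0 lists were called by camera in each of the 6 comparisons, with 4, 1, 5, 2, 4 and 1 at an unadjusted p under 0.05 in the order above. With fry 7, 1, 8 and 0 were called for layers at P3, layers at P7, the mean layer difference and the difference of age changes, the last with 1 at an unadjusted p under 0.05, against 17, 15, 20 and 13 with camera.

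Without 1 library the gene count for layers at P3 ranged from 668 (without P3 layer 2 replicate 2) to 1976 (without P3 layer 3 replicate 2), for layers at P7 from 14 (P7 layer 2 replicate 2) to 125 (P3 layer 3 replicate 2), and for age in layer 2 from 2799 (P3 layer 2 replicate 2) to 4952 (P3 layer 3 replicate 2). It ranged for age in layer 3 from 2266 (P3 layer 3 replicate 1) to 5212 (P3 layer 3 replicate 2), for the mean layer difference from 798 (P7 layer 2 replicate 2) to 1605 (P3 layer 3 replicate 2), and for the difference of age changes from 8 (P7 layer 3 replicate 1) to 102 (P3 layer 3 replicate 2). Called lists ranged from 16 to 21, 12 to 19, 13 to 16, 15 to 19, 17 to 23 and 10 to 18.

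With the replicate number as a block the gene counts were 1524, 68, 4084, 3336, 1305 and 31, the called lists 19, 17, 16, 17, 22 and 14, and the overlap of the layer calls 34. Residuals of libraries with the same number correlated at -0.189 to 0.214, and 5 of 18 such pairs lay above 0.1. Among libraries of other groups, 7 of 12 libraries correlated best with one of their own number. A weak factor shared by libraries of the same number is thus not excluded.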

Other observations

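The genes and gene families in this part were chosen only after their values were seen. Cilium genes outside the fixed lists were higher in P3 layer 2 than in P3 layer 3. Foxj1, the regulator of motile cilia, averaged 50 TPM in P3 layer 2, 5.28 TPM in P3 layer 3, 9.84 TPM in P7 layer 2 and 3.22 TPM in P7 layer 3 (layers at P3 2.96 ± 0.39, adjusted p = 0.000795). Meig1 (3.00 ± 0.33, adjusted p = 0.000317), Ccdc153 (2.29 ± 0.51, adjusted p = 0.014) and the ependymal gene Mia (2.37 ± 0.35, adjusted p = 0.00139) were higher in P3 layer 2 too. Of 66 genes of motile cilium families, 29 were higher and 37 were not called at P3 (median 1.04, camera p = 8.37e-16, p = 0.0219 with an estimated correlation). In layer 2, 22 of them fell and 1 rose between P3 and P7, and in layer 3, 4 fell and 7 rose.

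Genes of the Y chromosome differed between pools of pups. Eif2s3y was listed at 0, 0 and 8.35 TPM in the P3 layer 2 libraries, at 32.7, 23.7 and 98.9 TPM in P3 layer 3, at 28.4, 15.2 and 73.5 TPM in P7 layer 2 and at 16.2, 10.4 and 33.9 TPM in P7 layer 3. Uty was listed at 0 in all P3 layer 2 libraries and at 1.05, 2.28 and 3.54 TPM in P3 layer 3. Xist, which is expressed from the inactive X chromosome, was at 25.0, 21.1 and 35.9 TPM in P3 layer 2 and at 5.95, 14.3 and 0.382 TPM in P3 layer 3.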
